A study of Mus musculus with 6 samples.

How the data were processed

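Quadriceps RNA from 6 mouse samples was measured on 1 Affymetrix mouse array per sample. Per the labels' protocols, total RNA was extracted with Trizol, purified on a silica membrane, amplified and labelled with biotin as cDNA using the NuGEN Ovation system. The deposited values were probe set intensities on a linear scale. Per the submitters' processing notes the authors used GCOS and RMA, whose versions are not given in the sources used here. The linear scale was read from the values, which lay between 37.2 and 16069 with array medians of 56.6 to 58.6. RMA commonly ends on a log2 scale with equal distributions, and the upper quartiles of these arrays, 146 to 182, were not equal. Whether the authors converted the values back or scaled them again stays unknown. RMA summaries shrink small intensities toward a floor, which compresses fold changes of dim genes.

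Samples were grouped by the genotype in their labels into 3 knockout and 3 control samples. The labels do not say that the samples of a group came from separate animals, so p-values measure the spread between these samples, which may be partly technical. Each group held samples with a male and with a female pattern of sex-chromosome transcripts, and so more than 1 animal. The 45101 probe sets were paired with genes through the platform annotation. It listed 34958 probe sets with 1 gene symbol and 932 with several, and did not list 9211. Entrez identifiers of 34754 single-gene probe sets were found in the RefSeq table of assembly GRCm38.p6, and 0 symbols changed. The table was used for names and gene order, and no coordinates were taken from it. Each of 18194 genes was represented by its single-gene probe set with the highest mean over all 6 arrays, and 9012 of these genes had more than 1. A fixed list of genes restricted to other tissues, 36 of them measured, served as the background. Its 95th percentile was an intensity of 79.9, or 6.32 on the log2 scale.

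The deposited intensities were log2-transformed with no pseudocount and fitted with limma 3.58.1 in R 4.3.3 (lmFit, eBayes with trend, group as the only term). Tests were two-sided, with Benjamini-Hochberg adjustment over all genes and a threshold of 0.05. The number of arrays limits the precision, and 3 against 3 arrays cannot give an exact permutation p under 0.1. Of 40 fixed gene lists, 37 were tested with camera at a preset inter-gene correlation of 0.01, adjusted over the 37 lists. The other 3 lists (sex-chromosome transcripts, neighbours of Pofut1 on chromosome 2, and the background list) served as checks. Camera with an estimated correlation and fry were run beside it. The lists, tests, alternatives and the rule for named genes were fixed before the data were examined.

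The rule named Pofut1 and Acta1, then up to 12 genes per direction with the largest log2 fold change past the threshold and without overlap between groups. Where too few passed, places were filled from genes with an unadjusted p under 0.01, no overlap, and a group mean above the background percentile, named as not past the threshold. From each list the 2 members with the smallest p were named when none passed. Any other gene named was chosen after its values were seen.

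On simulated arrays with the means and residual spread of the real genes, 200 of 18194 genes were given log2 changes of 1 or 2. These were drawn only from genes with a mean above the background percentile, so the recovered shares do not cover dimmer genes. The limma fit of all arrays recovered 24% of genes changed by 1 and 77% of those changed by 2, with 8 unchanged genes called. Without the array labelled control replicate 3 it recovered 40% and 85%, with 7 unchanged genes called. The simulated genes were independent of each other, unlike real ones, so the simulation does not bear on the lists. It also gave every array the same residual spread, whereas the real array labelled control replicate 3 stood apart from the others. The recovered shares are therefore not the power of the real test over all arrays.

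Alternatives covered the replicate number as a block, quantile normalization, centring on array medians, array weights, other variance models, filters on dim genes, other uses of probe sets, sex as a covariate, and leaving out each array. In the filters, genes above the floor had a mean above the 90th percentile of the background list, 5.93 on the log2 scale. Alternatives added after seeing the data left out the array labelled control replicate 3 with sex as a covariate or with an estimated correlation, left out both arrays with a high Gapdh 3' over 5' ratio, or used that ratio as a covariate.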

Results

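Gene expression was measured in quadriceps muscle of 2-month-old C57/Bl6 mice. Pofut1 encodes protein O-fucosyltransferase 1, which adds O-linked fucose to EGF-like repeats of proteins such as the Notch receptors. The knockout group held 3 samples with a skeletal alpha-actin cre transgene and floxed Pofut1 alleles, and the control group held 3 samples with the same transgene and wild-type Pofut1. The comparison asked which transcripts differ in muscle when Pofut1 is deleted there. Intensities were read for 45101 probe sets, which gave values for 18194 named genes.

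The array labelled control replicate 3 stood apart from the other 5. Over all genes its log2 values correlated with theirs at 0.940 to 0.945, while the other 5 arrays correlated with each other at 0.980 to 0.991. The component that separated it carried 63.3% of the variance. In it, 577 genes lay more than 1 log2 unit above the mean of the other arrays and 1384 lay below, against totals of 81 to 181 genes for each other array. Its 3' over 5' intensity ratio was 10.5 for Gapdh and 5.85 for Actb, transcripts used to follow the integrity of RNA and the length of its cDNA. Knockout replicate 2 had ratios of 3.70 and 4.34, and the remaining 4 arrays had Gapdh ratios of 1.73 to 1.97. Xist, transcribed from the inactive X chromosome of females, had intensities of 1349 in knockout replicate 2 and 1414 in control replicate 2, and at most 67.6 elsewhere. The Y-linked gene Eif2s3y was 40.7 and 41.0 in these arrays and at least 1202 in the others, so each group held 1 sample with a female pattern.

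**Figure D1:**
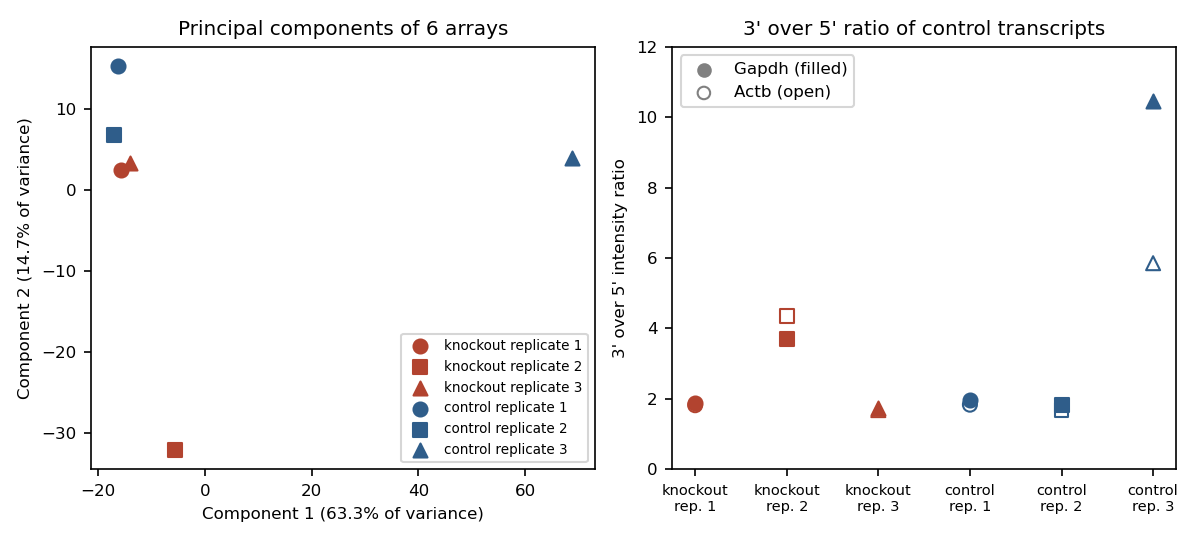
Left, the first and second principal components of the log2 values of all genes for each array (colour, group; symbol, replicate number); right, the 3' over 5' intensity ratio of Gapdh (filled) and Actb (open) for each array. Control replicate 3 lies far from the other arrays on the component that carries 63.3% of the variance and has a Gapdh ratio of 10.5, and knockout replicate 2 has the next highest ratio, 3.70.

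Pofut1 itself did not pass the test over all 6 arrays. Its brightest probe set read 220.1, 231.1 and 194.3 in knockout replicates 1 to 3 and 301.4, 379.8 and 90.6 in the arrays labelled control replicates 1 to 3. The log2 fold change was -0.02 ± 0.52 (SE), with an adjusted p of 0.998 in limma and an exact two-sided permutation p of 1. The array labelled control replicate 3 had the lowest value of all 6, which ran against its label. In that array 1384 genes lay more than 1 log2 unit below the mean of the other arrays. A low value there therefore says little about genotype. Without that array the log2 fold change was -0.66, or 1.58-fold lower in the knockout. The unadjusted limma p was then 0.0079 and did not pass adjustment. Without control replicate 1, control replicate 2 or knockout replicate 3 the log2 fold change was above 0, at 0.21, 0.38 and 0.05. All of these fits kept the array labelled control replicate 3. The other probe sets of Pofut1 read 44.3 to 74.9 and were at or below the background percentile of 79.9 in every array. Whether any of them lies inside the deleted part of the gene is not given in the sources used here, and a probe set outside it checks nothing about the deletion. Acta1, skeletal alpha-actin, whose promoter drives the transgene, had a log2 fold change of 0.13 ± 0.08 (SE; adjusted p = 0.971).

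**Figure D2:**
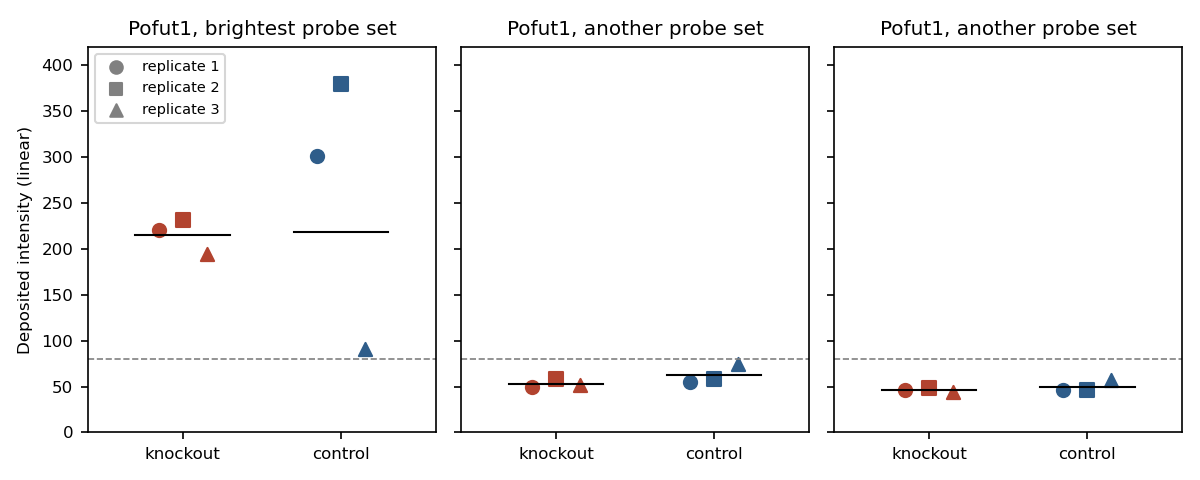
Deposited linear intensity of each Pofut1 probe set in every array; lines are geometric means of 3 arrays and the dashed line is the 95th percentile of background genes (79.9). In the brightest probe set the knockout arrays lie between 194.3 and 231.1, below control replicates 1 and 2 and above control replicate 3.

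No gene passed the threshold between knockout and control muscle, and the differences below are given as values. They are ranked only among genes with an unadjusted p under 0.01, no overlap and a group mean above background, and genes outside these limits had larger differences. Within them the highest values in the knockout were those of Nr4a2 and Nr4a1, nuclear receptors of the immediate early class, with log2 fold changes of 1.72 ± 0.44 and 1.33 ± 0.28 (SE). Hdac9, a class IIa histone deacetylase of muscle, had a log2 fold change of 1.30 ± 0.27, and the deubiquitinase gene Otud1 had 1.19 ± 0.22. Metabolic enzymes among the 12 were Acly, which makes cytosolic acetyl-CoA for lipid synthesis, at 1.17 ± 0.25, Idi2, an isopentenyl-diphosphate isomerase, at 1.27 ± 0.22, and the pentose phosphate enzyme Tkt at 0.98 ± 0.25. Tmem242, Tmem181a, Tnfrsf19, Orm1 and the smooth muscle gene Lmod1 completed them, at 0.98 to 1.29. Within the same limits values were lowest against control for Ifi202b, an interferon-activated gene, at -2.13 ± 0.51, for Phlda3, a p53 target that restrains Akt, at -1.65 ± 0.27, and for Shisa4 at -1.35 ± 0.23. Ucp3, the muscle mitochondrial uncoupling protein, was 2.20-fold lower (log2 fold change -1.14 ± 0.20), Trim12a had -1.27 ± 0.36, and the mitotic gene Hmmr had -1.06 ± 0.27. Ccdc85b, Cadm3 and the vesicle protein gene Vamp2 had values of -0.98 to -0.94, close to that of the phosphatase gene Cdc14a, and 2 further places went to a predicted gene and a microRNA gene. Idi2 in the control group and Hmmr, Trim12a and the microRNA gene in the knockout group had means below the background percentile, so the sizes of these differences are uncertain. For each of these genes all 3 knockout values lay on one side of all 3 control values, as the rule required, and the adjusted p was 0.971.

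Limma called 0 genes higher and 0 lower, and ordinary t statistics of the same model also called 0. At an unadjusted p under 0.05 limma gave 469 genes, 182 higher and 287 lower, where chance alone gives 910, and ordinary t statistics gave 615. Of all genes, 1640 (9.01%) had no overlap between the groups, where chance gives 10%. Without the array labelled control replicate 3, 0 genes passed (lowest adjusted p 0.395) and 1090 had an unadjusted p under 0.05, 371 higher and 719 lower, of which 352 were shared with the 469. Leaving out knockout replicate 1, 2 or 3 lowered that count to 284, 276 and 284.

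**Figure D3:**
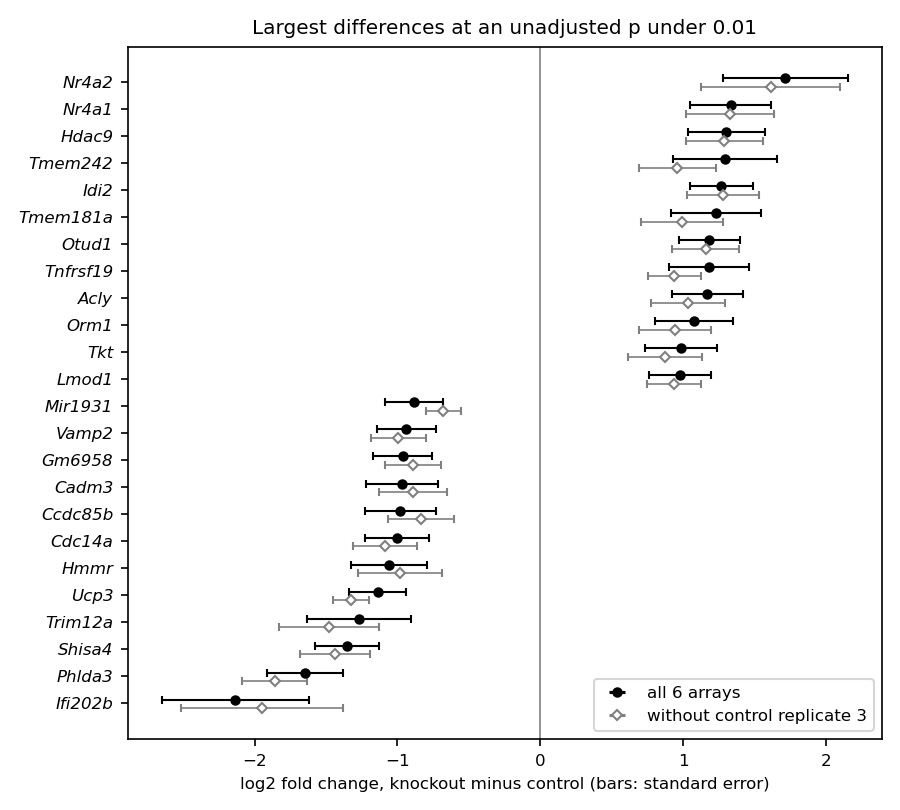
Log2 fold change, knockout minus control, with its standard error, of the 24 named genes with the largest differences at an unadjusted p under 0.01, over all 6 arrays (filled circles) and without control replicate 3 (open diamonds). No gene passed adjustment. Values run from -2.13 for Ifi202b to 1.72 for Nr4a2. Each keeps its sign without control replicate 3, as it must, since the genes were chosen for no overlap between groups.

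Genes of adipocytes and fat synthesis were higher in the knockout as a group. Of 22 measured members 21 had higher values, with a mean log2 fold change of 0.64 and a median of 0.60, and the list passed camera at an adjusted p of 1.61e-09. The call was lost with an estimated correlation (adjusted p = 0.641 with an estimated correlation). Fasn, fatty acid synthase, had a log2 fold change of 1.42 ± 0.41 and Acly, which acts upstream of it, 1.17 ± 0.25. Adjusted over the list alone 0 members passed, as over all genes, and 6 members had an unadjusted p under 0.05 in limma. In the array labelled control replicate 3 the list lay low, with a median of -0.81 against 4 other arrays. It was low also in knockout replicate 2, the other array with high 3' over 5' ratios, with a median of -0.34 against the other knockout arrays. There only its adipocyte-restricted members had the lowest mean of the group (8.38 on the log2 scale, against 8.76 and 9.69 in knockout replicates 1 and 3). Its lipogenic members had a mean of 9.21, between 8.96 and 9.51 in these 2 arrays. Without the array labelled control replicate 3 the mean log2 fold change of the list was 0.46, with 19 of 22 members higher and an adjusted p of 7.28e-05 (adjusted p = 0.726 with an estimated correlation). The list also passed in 5 of the 9 other splits of the 6 arrays into equal groups, at adjusted p of 3.88e-07 to 0.0224. Every such split leaves unequal numbers of knockout arrays on its sides, so a difference by genotype could also pass there. Whether the call follows genotype is therefore not settled by these splits.

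Immediate early genes, transcribed within minutes of a stimulus, were also higher as a list. Of 24 members 18 had higher values (mean log2 fold change 0.22, median 0.13), camera gave an adjusted p of 0.00265, and 0 passed adjusted over the list alone. The call was lost with an estimated correlation (adjusted p = 0.641 with an estimated correlation). Nr4a1 and Nr4a2 led the list, whereas Egr1 had a log2 fold change of -0.62 ± 0.32. The call was also lost without control replicate 1 (adjusted p = 0.0845) and without the array labelled control replicate 3 (adjusted p = 0.101, mean 0.08, median 0.04), in which the list had a median of -0.30 against 4 other arrays.

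Fast-twitch fibre genes were slightly higher in the knockout and oxidative phosphorylation genes slightly lower, by list. Of 20 fast-twitch genes 18 had higher values, with a mean log2 fold change of 0.08 and a camera adjusted p of 0.00773 (adjusted p = 0.641 with an estimated correlation). Tnnt3, fast troponin T, had 0.19 ± 0.08 and Myh4, the fastest myosin heavy chain, 0.13 ± 0.08. Of 50 genes of mitochondrial oxidative phosphorylation 36 had lower values, with a mean of -0.06 and an adjusted p of 0.0439 (adjusted p = 0.784 with an estimated correlation). Atp5d, a subunit of ATP synthase, had -0.24 ± 0.09 and Ndufv1, of complex I, -0.24 ± 0.09. Adjusted over the list alone 0 members of either passed, as over all genes. The fast-twitch call ended with quantile normalization (adjusted p = 0.191), and the oxidative phosphorylation call with the replicate number as a block (adjusted p = 0.121), with array weights (0.705) and with the mean of probe sets (0.0592). The fast-twitch call also ended without knockout replicate 3 (adjusted p = 0.182), control replicate 1 (0.223) or the array labelled control replicate 3 (0.0523), and the other without knockout replicate 2 (0.789), control replicate 1 (0.106), control replicate 2 (0.152) or the array labelled control replicate 3 (0.281).

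Slow-twitch fibre genes, in contrast, varied between samples of both groups. Of 18 members 12 had higher values in the knockout (mean log2 fold change 0.27, camera adjusted p = 0.400). Tnnc1, slow troponin C, had 1.26 ± 0.79 and Ankrd2 had -0.49 ± 0.28. The list stood high in both arrays with high 3' over 5' ratios, with medians of 0.51 in the array labelled control replicate 3 and 0.48 in knockout replicate 2 against other arrays. Without the array labelled control replicate 3 the mean was 0.55 and the adjusted p 0.0295 (adjusted p = 0.777 with an estimated correlation). Glycolysis and glycogen genes (14 of 22 higher, adjusted p = 0.162) included the glycogen branching enzyme Gbe1 at 0.73 ± 0.24 and the phosphorylase kinase gene Phkg1 at 0.23 ± 0.11. Genes of fatty acid uptake and oxidation were split, 14 higher and 14 lower, with an adjusted p of 0.289. In that list Ucp3 alone passed adjusted over the list alone (adjusted p = 0.0208), against 0 over all genes, and the oxidation enzyme Acaa2 had -0.23 ± 0.11.

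Genes of the Notch machinery were higher as a list, whereas Notch targets did not pass. Of 27 receptors, ligands and pathway components 21 had higher values, with a mean log2 fold change of 0.14, a median of 0.06 and a camera adjusted p of 0.0263 (adjusted p = 0.641 with an estimated correlation). The ligand gene Dll1 had 0.33 ± 0.16 and the coactivator gene Maml1 0.44 ± 0.23. Dll1 was below background in the control group. The call was lost without knockout replicate 2 (0.0621), knockout replicate 3 (0.0516), control replicate 1 (0.106) and the array labelled control replicate 3 (0.281, mean 0.05), where the list had a median of -0.28 against 4 other arrays. It was lost also over genes above the 90th percentile of background (0.0944), over genes above the median level (0.234) and with array weights (0.197). The mean of probe sets (0.0592) and every probe set (0.0966) ended it as well. Of 16 Notch target genes 10 had lower values (mean -0.10, adjusted p = 0.607), with Ccnd1, cyclin D1, at -0.94 ± 0.34 and Notch3 at 0.79 ± 0.42. The list of O-fucose and EGF-repeat glycosylation genes had 17 of 22 members lower (mean -0.09, adjusted p = 0.366). Besides enzymes of O-linked fucose it holds enzymes that add other sugars, transporters and genes of fucose supply. Among the lower members was Gmds, which acts in the synthesis of GDP-fucose, at -0.81 ± 0.38, though its mean in the knockout group was below background. The other gene named from that list by the rule, Slc35c1, was below background in both groups. Without the array labelled control replicate 3 that list, which includes Pofut1, had a mean of -0.20 and an adjusted p of 0.00665 (adjusted p = 0.726 with an estimated correlation). Adjusted over the list alone 0 members of these 3 lists passed, as over all genes.

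Vessel genes were higher in the knockout by list and dividing-cell genes lower. Of 18 smooth muscle and pericyte markers 13 had higher values (mean log2 fold change 0.20, camera adjusted p = 0.0263, and adjusted p = 0.641 with an estimated correlation), and Lmod1 passed adjusted over the list alone (adjusted p = 0.0476) though not over all genes. Mylk, the smooth muscle myosin kinase, had 0.31 ± 0.14. Of 21 endothelial markers 15 had higher values (mean 0.16, adjusted p = 0.0263, and adjusted p = 0.641 with an estimated correlation), with the endothelial cadherin gene Cdh5 at 0.57 ± 0.19 and Vwf at 0.38 ± 0.22. Of 25 cell cycle genes 20 had lower values (mean -0.20, adjusted p = 0.0243, and adjusted p = 0.784 with an estimated correlation), with the replication gene Mcm6, below background in the knockout group, at -0.63 ± 0.26 and Ccna2, cyclin A2, at -0.75 ± 0.37. Adjusted over the list alone 0 endothelial or cell cycle genes passed, as over all genes. Only 12 of the 25 cell cycle genes were above background. Over genes above the 90th percentile of background all 3 calls ended (0.0528 for the cell cycle and 0.0944 for both vessel lists). They ended also over genes above the median level (0.486 for the cell cycle, 0.134 for smooth muscle and 0.143 for endothelium). Over every probe set the endothelial list was at 0.0781. That list lay low in both arrays with high 3' over 5' ratios, with medians of -0.27 in the array labelled control replicate 3 and -0.19 in knockout replicate 2 against other arrays. The smooth muscle list had 0.05 and -0.09 there. Without control replicate 1 the adjusted p was 0.364 for both vessel lists and 0.800 for the cell cycle. Without knockout replicate 3 it was 0.0721 for smooth muscle, 0.105 for endothelium and 0.0721 for the cell cycle. Without knockout replicate 1 it was 0.104 for smooth muscle and 0.141 for endothelium, without control replicate 2 it was 0.0620 for smooth muscle, and without knockout replicate 2 it was 0.105 for the cell cycle. The cell cycle list without the array labelled control replicate 3 had a mean of -0.34 and an adjusted p of 0.000703 (adjusted p = 0.726 with an estimated correlation).

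Immune lists had mostly lower values that did not pass over all 6 arrays. Of 28 macrophage and monocyte markers 20 were lower (mean log2 fold change -0.21, camera adjusted p = 0.0676), among them Folr2 at -0.63 ± 0.25 and Ms4a7, below background in the knockout group, at -1.14 ± 0.46. Of 25 interferon-stimulated genes 18 were lower (mean -0.14, adjusted p = 0.167), with Oasl2 at -0.68 ± 0.28 and Oas1a at -0.55 ± 0.28. Without the array labelled control replicate 3 both lists passed, with means of -0.37 and -0.26 and adjusted p of 0.00229 and 0.00417, and not with an estimated correlation (adjusted p = 0.777 and adjusted p = 0.726 with an estimated correlation). Macrophage markers also passed without knockout replicate 1 (0.000135) and control replicate 2 (0.0107), and interferon genes without knockout replicate 1 (0.0376). Lymphocyte markers had an adjusted p of 0.909 and erythroid markers 0.814.

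Lists tied to innervation, regeneration and the surroundings of the fibre did not pass. Neuromuscular junction components, genes responsive to denervation, and satellite cell and myogenic factors had adjusted p of 0.768, 0.798 and 0.498. Hdac9 passed adjusted over the denervation list alone (adjusted p = 0.0486), though neither over all genes nor without the array labelled control replicate 3 (adjusted p = 0.0764), while Runx1 in the same list had a log2 fold change of -0.87 ± 0.47, and 18 of its 26 members were lower. Developmental muscle genes had an adjusted p of 0.400, and passed on the lower side without knockout replicate 1 (0.00598) and without the array labelled control replicate 3 (0.0264, mean -0.28), the latter not with an estimated correlation (adjusted p = 0.726 with an estimated correlation). Interstitial matrix genes were split, 18 higher and 16 lower (adjusted p = 0.902), with the collagen VI genes Col6a1 at -0.36 ± 0.10 and Col6a2 at -0.44 ± 0.14. Without knockout replicate 1 that list passed on the lower side (0.0415). Basal lamina genes (0.221), fibroblast markers (0.607), tendon markers (0.0676) and nerve markers (0.193) did not pass over all arrays. Basal lamina genes passed on the higher side without knockout replicate 2 (0.00809) or control replicate 2 (0.0496), tendon markers without control replicate 2 (0.00361) or knockout replicate 3 (0.0194), and nerve markers without control replicate 2 (0.0318).

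Among lists of signalling and stress, glucocorticoid-responsive genes had 12 of 18 members higher (adjusted p = 0.157), with Per1 at 1.14 ± 0.38 and Sgk1 at 0.33 ± 0.12. That list had 9 of 18 members higher and a mean of -0.005 without the array labelled control replicate 3, and Mt1, Mt2 and Serpina3n, chosen after their values were seen, then passed as lower adjusted over the list alone (adjusted p = 0.0374), with log2 fold changes of -0.93, -1.42 and -0.76, Serpina3n being below background in the knockout group. Circadian genes had an adjusted p of 0.325, with Per1 higher and Dbp at -0.33 ± 0.14. Atrophy and autophagy genes (adjusted p = 0.487) included Ddit4 at 1.63 ± 0.63 and Becn1 at 0.40 ± 0.13. The small heat shock protein gene Hspb1 had -0.52 ± 0.15 in a heat shock list with an adjusted p of 0.996. Adjusted p was 0.0555 for Wnt pathway genes, 0.325 for TGF-beta and BMP response, 0.607 for muscle growth factors, 0.692 for calcium handling, 0.798 for the unfolded protein response, 0.814 for polyamine metabolism and 0.814 for senescence. Without control replicate 2 the glucocorticoid (0.00361), circadian (0.0487), atrophy (0.0428) and Wnt (0.0212) lists passed on the higher side, as did the Wnt list without knockout replicate 2 (0.0414). In the array labelled control replicate 3 the glucocorticoid and Wnt lists had medians of -0.69 and -0.66 against 4 other arrays. The test, mean and median did not share one sign for fatty acid oxidation, TGF-beta response, atrophy, calcium handling, erythroid and polyamine genes. Over all 6 arrays only Lmod1, Ucp3 and Hdac9 passed adjusted over the list alone among all 37 lists. Lmod1, Ucp3, Hspb1, Mt1, Mt2 and Serpina3n did so without the array labelled control replicate 3, and Hdac9 did not (adjusted p = 0.0764). In addition, fry gave adjusted p of 0.820 or more for every list. All 8 lists past the threshold with the preset correlation lost it with an estimated one. The number that passed was 1 without control replicate 1, 4 without knockout replicate 3 and 14 without control replicate 2.

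**Figure D4:**
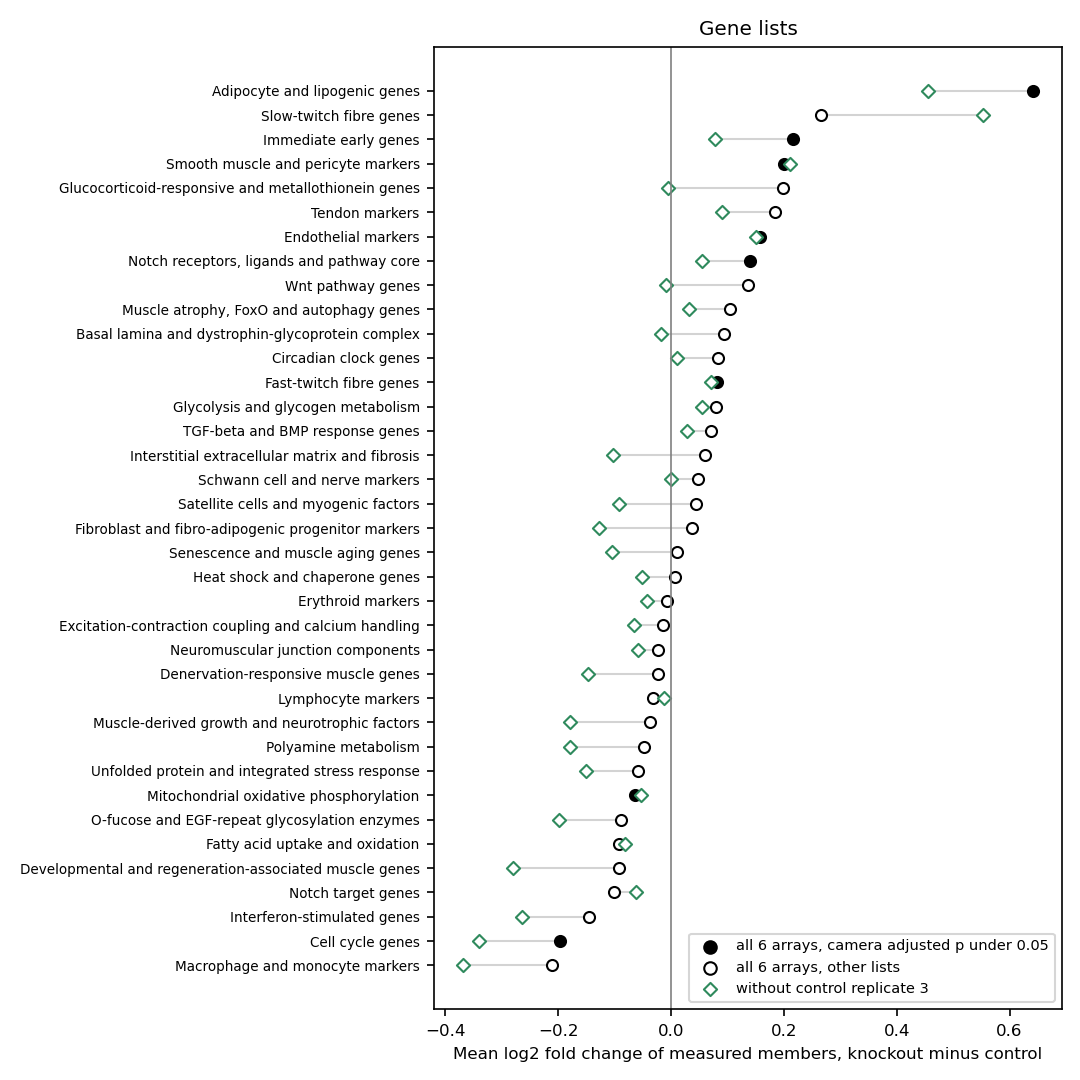
Mean log2 fold change, knockout minus control, of the measured members of each of 37 gene lists over all 6 arrays (circles; filled, camera adjusted p under 0.05 with the preset correlation) and without control replicate 3 (diamonds). The adipocyte and lipogenic list has the highest mean, 0.64, and 0.46 without control replicate 3; none of the 8 filled circles kept its call with an estimated correlation.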

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

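The tests of cDNA length with no array shared, of tissue identity, of a knockout sample with a control label, of adipocyte content, and of the array labelled control replicate 3 as the whole source of the lipogenic pattern were chosen only after the results were seen. Probe sets for the phage P1 cre gene, which lie outside the gene comparisons, read 842.6 to 5184 over the 6 arrays, while the probe sets for bioB, bioC and bioD read at most 69.97. Knockout minus control, the mean of these cre probe sets was -0.42 on the log2 scale (10.95 ± 0.20 against 11.37 ± 0.57, SD, n = 3 each; exact two-sided permutation p = 0.3, where 0.1 is the smallest possible), and -0.75 without the array labelled control replicate 3, which read 10.72, against 11.75 and 11.65 in the other controls and 10.72 to 11.07 in the knockout arrays.

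The array labelled control replicate 3 had 1482 genes lower and 587 genes higher by at least 1 log2 unit than the 4 arrays other than itself and knockout replicate 2. A tissue other than skeletal muscle was argued against, since its fast-twitch genes had a median deviation of -0.0642, and a knockout sample with a control label does not account for its distance, since its mean correlation with the knockout arrays was 0.943, against 0.980 as the lowest among the others, though whether its label is also wrong stays open. Short or degraded cDNA is a candidate explanation for the lower genes. Over 1600 genes at least 1 log2 unit lower than in control replicates 1 and 2, knockout replicate 2, with the next highest Gapdh 3' over 5' ratio, lay below the other knockout arrays (median -0.18, and -0.168 ± 0.013 SE over genes against genes of matched level). Of these genes 69.6% were lower in it, against 51.9% of matched genes. The SE does not measure the spread between arrays. Knockout replicate 2 was also the only array of its group with a female pattern, so its deviation may include other differences between samples. For 361 higher genes above background in control replicates 1 and 2 the same difference was 0.0379 ± 0.024, which leaves it open, and the medians of -0.20 and 0.0571 over genes chosen against 4 arrays decide nothing, since knockout replicates 1 and 3 entered both the choice and the deviation. Jhy, chosen after its values were seen, read 1119 in that array and at most 41.9 in the others, and no test here covered such genes, nor was a biological explanation tested.

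The adipocyte and lipogenic genes were higher in the knockout arrays with a mean of 0.46 (log2) without the array labelled control replicate 3, so that array alone was not the source. With the mean of the adipocyte-restricted genes as a covariate, the lipogenic enzymes had a mean log2 fold change of 0.62, with 9 of 12 higher. Camera gave p = 3.05e-05 for them, and p = 0.0962 with an estimated correlation. A larger adipocyte content as the whole cause stays open, since a mean of few genes may follow that content imprecisely and leave part of it unadjusted. The set of lipogenic enzymes also held the regulators Pparg and Cebpa and the lipases Lipe and Pnpla2, so its values are not those of lipogenic enzymes alone. The median of the adipocyte-restricted genes was 0.37 below that of the enzymes, or a difference of -0.37 with a 95% bootstrap interval of -0.83 to 0.19; this exceeded its standard error of 0.27, a bound set too loosely, and does not part the sets. Adipocyte content may contribute, since knockout replicate 3 had the highest mean of the adipocyte-restricted genes (9.69 on the log2 scale, others 8.11 to 8.79). Whether muscle fibres or vessels also express members of that set was not tested. In the control group Car3 and Fabp4 had means of 12.53 and 12.15 (log2). Lep, Ucp1 and Cidea, at 6.13, 5.74 and 5.54, were below background there. The mean of the set is thus an uncertain measure of adipocyte content. The abundant Fabp4 and Adipoq had log2 fold changes of 0.12 and 0.58, and 0.15 and -0.05 without the array labelled control replicate 3. A difference in feeding stays open, since genes induced by fasting had a median of 0.12, and -0.02 without the array labelled control replicate 3, with members on both sides, and the genotype is a further open explanation.

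The real grouping gave 469 genes at an unadjusted p under 0.05, and 5 of the 10 splits of the 6 arrays, the real one included, gave as many, the highest other 1238. It gave 8 lists past the threshold, and 5 of the 10 splits, the real one included, gave as many, the highest other 13. The adipocyte and lipogenic list had an adjusted p of 1.61e-09 in the real grouping and passed in 5 of the 9 other splits, at 3.88e-07 to 0.0224, the lowest where knockout replicate 1 was put with the arrays labelled control replicates 1 and 3. With 10 splits a share under 0.05 cannot be reached. Every split other than the real one leaves unequal numbers of knockout arrays on its sides, so a difference by genotype could also show there. The split with 1238 genes put knockout replicate 1 with control replicates 1 and 2, against the 2 arrays with high 3' over 5' ratios and knockout replicate 3, which points to a structure of the samples other than genotype.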

How the results depend on the processing

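Alternatives that left out the array labelled control replicate 3 together with another change, or both arrays with high 3' over 5' ratios, or that used the Gapdh ratio as a covariate, were chosen after seeing the data. Under every alternative run, limma or ordinary t statistics called 0 genes higher and 0 lower, and 0 of the 92 named genes other than Pofut1 passed. The count at an unadjusted p under 0.05 (469) was 786 without the variance trend, 709 over every probe set, 303 among genes above the median level and 1854 with array weights. It was 1169 with the Gapdh ratio as a covariate, 1362 without both arrays with high ratios, 1477 without the array labelled control replicate 3 with sex as a covariate, and 276 to 1090 when single arrays were left out. Pofut1 (log2 fold change -0.02) ranged from -0.71 without both arrays with high ratios, and -0.66 without the array labelled control replicate 3, to 0.38 without control replicate 2, and was above 0 also without knockout replicate 3 (0.05) and control replicate 1 (0.21). The fits with values above 0 all kept the array labelled control replicate 3. Smox was 0.54 as the mean of its probe sets, against -0.52 from its brightest. Filters and left-out arrays leave fewer genes or samples. For the other settings the cause was not tested.

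Same-numbered samples did not deviate together (correlations of 0.19, -0.15 and -0.11), so the numbers were not taken to pair samples. With the replicate block 377 genes had an unadjusted p under 0.05, 0 passed and 9 lists passed: macrophage markers (0.0223) and Wnt genes (0.0473) came in and oxidative phosphorylation (0.121) went out.

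The number of lists past the threshold (8) was 4 over genes above the floor and 4 over genes above the median level, 0 with an estimated correlation, 0 with fry and 0 without the array labelled control replicate 3 with an estimated correlation, and 1 to 14 when single arrays were left out (1 without control replicate 1, 14 without control replicate 2). Adjusted p of the 8 lists was 0.641 to 0.784 with an estimated correlation, 0.820 to 0.846 with fry, and 0.726, 0.777 (fast-twitch) or 0.829 (oxidative phosphorylation) without the array labelled control replicate 3 with an estimated correlation. With the preset correlation the adipocyte and lipogenic list passed under all 20 alternatives (adjusted p 1.13e-14 to 0.0018). Over genes above the floor, adjusted p was 0.0528 for the cell cycle and 0.0944 for the endothelial, Notch and smooth muscle lists. Over genes above the median level these were 0.486, 0.143, 0.234 and 0.134. With the mean of probe sets the Notch and oxidative phosphorylation lists were at 0.0592. Over every probe set the endothelial list was at 0.0781 and Notch at 0.0966, while basal lamina (0.0464), glycolysis (0.0278), interferon (0.0464), macrophage (0.0074), slow-twitch (0.0305) and tendon (0.0305) lists passed. With quantile normalization fast-twitch was at 0.191, and macrophage and Wnt lists passed (0.0478). Macrophage markers passed also with median centring (0.0241) and with sex as a covariate (0.0453).

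With array weights oxidative phosphorylation (0.705) and Notch (0.197) went out, and interferon (0.00417), macrophage (0.000276), O-fucose (0.0166) and slow-twitch (0.00732) lists came in. With the Gapdh ratio as a covariate Notch was at 0.0534, and interferon and macrophage (0.0168) and slow-twitch (0.0269) came in. Without both arrays with high ratios, immediate early (0.126), oxidative phosphorylation (0.999) and Notch (0.479) went out, and erythroid (0.0475), interferon (0.0179), macrophage (0.0204) and O-fucose (0.0287) came in. Without the array labelled control replicate 3 and with sex as a covariate, fast-twitch (0.0835), immediate early (0.0867), oxidative phosphorylation (0.156) and Notch (0.195) went out. In that setting developmental (0.0128), interferon (0.00282), macrophage (3.91e-05), O-fucose (0.00561) and slow-twitch (6.1e-05) lists came in, and interstitial matrix passed on the lower side (0.0223), the reverse of its direction over all arrays.

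Leaving out single arrays, adjusted p ran from 0.000703 to 0.800 for the cell cycle, 0.00196 to 0.364 for endothelium, 7.16e-05 to 0.223 for fast-twitch, 0.000292 to 0.101 for immediate early genes, 0.00244 to 0.789 for oxidative phosphorylation, 0.0144 to 0.281 for Notch and 0.00273 to 0.364 for smooth muscle. Of lists not past the threshold it ran from 0.00809 to 0.968 for basal lamina, 0.0487 to 0.917 for circadian, 0.00598 to 0.964 for developmental, 0.00361 to 0.955 for glucocorticoid, 0.00417 to 0.733 for interferon and 0.0415 to 0.840 for interstitial matrix genes (reversed without knockout replicate 1, at 0.0415). It ran from 0.000135 to 0.804 for macrophage, 0.0428 to 0.733 for atrophy, 0.00665 to 0.897 for O-fucose, 0.0318 to 0.727 for nerve, 0.0295 to 0.987 for slow-twitch, 0.00361 to 0.654 for tendon and 0.0212 to 0.581 for Wnt lists. Signal over background limits the rest: 9848 genes had a mean above the background percentile.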

Other observations

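The tests of neighbours of Pofut1, of the wider window and of the adipocyte-restricted and lipogenic genes were chosen only after results were seen. Several of the named genes lie near each other. On chromosome 1, Lmod1 (log2 fold change 0.98), Shisa4 (-1.35) and Phlda3 (-1.65) fall within 6 tested genes, and Dusp23 (-0.78, chosen after its values were seen and below background in the knockout group) and Ifi202b (-2.13) lie 6 and 8 tested genes from Cadm3 (-0.97). On chromosome 17, Tmem242 (1.29) and Tmem181a (1.23) lie 7 tested genes apart, whereas the genes between them, looked up after these values were seen, ran from -0.59 for Zdhhc14 to 0.05 for Ldhal6b, which was below background.

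A hypothesis is that some of these genes differ through linked stretches of genetic background that the groups do not share. Among 45 genes with an unadjusted p under 0.01, no overlap and a value above background, 2 pairs lay within 5 tested genes of each other, where 10000 random draws had a median of 0 (permutation p = 0.108). Within 10 tested genes there were 6 pairs, against a median of 1 in random draws (permutation p = 0.0016). The second result may reflect linkage, but its window was set after the pairs were seen, and 3 of its pairs come from 1 group of genes. Around Pofut1 itself, 10% of neighbours had no overlap between the groups, or 2 of 20, as chance gives, a count too small to decide on a stretch around the floxed gene.

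Further hypotheses came from Idi2 and Phlda3, whose lists were written without them. Sterol synthesis genes and SREBP2 targets had 9 of 15 members higher with a mean log2 fold change of 0.11, and -0.04 without the array labelled control replicate 3. The unadjusted p from camera in limma was 0.142, and although 0.05 or more had been set beforehand as the bound against this hypothesis, a p that misses a threshold does not exclude it. Target genes of p53 did not pass as lower, the direction of Phlda3: 14 of 21 had higher values, with a mean of 0.06 ± 0.07 (SE over members), and -0.02 without the array labelled control replicate 3. The unadjusted p from camera in limma was 0.0603, upward. An upward direction had been set beforehand as a bound against this hypothesis, but the mean lay within its standard error of 0 and changed sign without that array, so the hypothesis stays open. Of the 5 lists in this family, adjusted p was 0.177 and 0.10 for these and 0.363 for genes induced by fasting. The lipogenic enzymes had 1.75e-09 and the adipocyte-restricted genes 0.00197. These sets divide the adipocyte and lipogenic list that had already passed, so their p-values are no separate support. Their small p-values also lower the adjusted p of the sterol and p53 lists in this family. With an estimated correlation the unadjusted p from camera was 0.0341 for the lipogenic enzymes and 0.213 for the adipocyte-restricted genes. Neither passes the threshold when adjusted over the 5 lists. The adipocyte-restricted genes did not pass without the array labelled control replicate 3, where their mean was 0.28 and their median 0.13. The unadjusted p from camera in limma was then 0.0680 for them and 3.97e-07 for the lipogenic enzymes. Among 10092 probe sets with no single gene, 0 passed in limma, where 173 had an unadjusted p under 0.05.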
